A study of Homo sapiens with 4 samples.

How the data were processed

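RNA sequencing was done on 4 libraries of cells labelled as the human osteosarcoma line MG63, 2 transfected with a control siRNA and 2 with an siRNA against KLF11, all harvested 48 hours after transfection. Per the labels' protocols, total RNA was extracted on columns, treated with DNase and enriched for polyadenylated RNA by magnetic beads. The authors deposited FPKM values, which are fragments normalised for gene length and library size, with 2 decimals for 57905 Ensembl gene identifiers, 1 column per library. Per the submitters' processing notes, Trim Galore 0.5.0, RSEM 1.3.1 and the human build hg19 (GRCh37) were used. The aligner, the annotation release, the strand setting and any filter are not given in the sources used here.

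FPKM divides by gene length and by the library's fragments, so a few abundant genes that change can move all others slightly, and no read count or depth can be had from it. RSEM splits reads among transcripts they match, so levels of genes with near-identical copies or pseudogenes, such as POU5F1, actins, keratins, HSPA1A and HSPA1B, histones and ribosomal proteins, are uncertain. Reads of overlapping or antisense genes cannot be told apart without the strand setting. Because the genome and annotation at hand were of another build, no coordinates are given. Gene symbols come from the table itself, where 5463 identifiers have none (736 of those tested) and 27 symbols had been turned into dates by a spreadsheet. Of 15320 tested identifiers, 14507 (94.7%) matched a current Ensembl name table, and the identifiers printed without a symbol did not.

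The groups were taken from the sample titles, and each column was matched to its sample by name, leaving 0 columns unmatched. Replicates were compared before they were averaged. Pearson correlations of log2 values across genes, which are not independent replicates, were 0.982 between the controls, 0.976 between the KLF11 siRNA libraries and 0.894 to 0.930 between groups. The median SD of log2 values was 0.0871 in control and 0.126 in KLF11 siRNA libraries, and at most 0.548% of tested genes had identical values in a pair, so no pair of libraries was counted as 1 sample. The first principal component held 81.4% of the variance and separated the groups, with KLF11 siRNA replicate 1 at 58.1 and replicate 2 at 33.8 against -47.6 and -44.4 for the controls. The labels give no sequencing batch or date.

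Genes with a mean FPKM of at least 1 over the 4 libraries were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend) on log2(FPKM + 1), as 2 groups with no block, with Benjamini-Hochberg adjustment and a threshold of 0.05. A fold change on this scale understates the change of low genes. Gene lists, 34 in number with 748 genes, were fixed before the data were examined, and 32 with at least 5 tested members were tested with camera at a preset correlation of 0.01, two-sided and adjusted over the lists, with camera at an estimated correlation and fry beside it. Of the listed genes, 7 were not analysed here, namely KLF14, MMP12, UHRF1, CCL5, ACACA, HIST1H3B and PECAM1. A count adjusted over the list alone uses only that list's p-values.

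Genes named were fixed by a rule written before the data were examined: KLF11, the 10 largest rises and the 10 largest falls past the threshold whose groups do not overlap, up to 4 members with the smallest p of each list, and YAP1, WWTR1, TEAD1, TEAD4, CTGF, CYR61, ANKRD1, SOX2, KLF4, MYC and KLF10. Members behind counts of 5 or fewer, and genes of 3 further marker lists (pluripotency, early endoderm, abundant mesenchymal genes), were named after their values had been seen. Some genes the rule selects are not reported here.

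The tests were checked on simulated data for the comparison of KLF11 siRNA with control siRNA, 2 libraries each, with 15320 genes of which 200 were changed, in 5 runs. Of the changed genes, 92.8% were recovered at a log2 change of 1 and 99.8% at a log2 change of 2, while 9.39% of the calls were false, above the nominal 5%. A shifted list was called in 100% of runs and unshifted lists in 0%. Genes were simulated as independent and lists drawn at random, so this does not measure false calls of lists whose genes move together. The simulated 200 changed genes were also far fewer than the 5400 called in the data.

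The alternatives tried were pseudocounts of 0.1 and 5, no filter and a filter of mean FPKM 5, scaling to TPM, median-of-ratios scaling, quantile normalization, eBayes without a trend and with robust estimation (statmod 1.5.0), the replicate number as a block, each library left out in turn, a minimum log2 change of 1 and an adjusted p of 0.1. TPM scaling without the mitochondrially encoded genes was added after their share was seen to differ between libraries. Figures were drawn with matplotlib 3.10.9.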

Results

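Messenger RNA was measured by sequencing of polyadenylated RNA in cells labelled MG63, a human osteosarcoma line grown from a bone tumour. The cells were transfected with a control siRNA or with an siRNA against KLF11 and harvested 48 hours later. Each group held 2 libraries, and the gene table gave FPKM values for 57905 gene identifiers, with no counts, so the read depth of each library is unknown. The FPKM of the libraries summed to 577849 and 582522 in control siRNA replicates 1 and 2 and to 591043 and 604498 in KLF11 siRNA replicates 1 and 2. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Unless stated otherwise, values are given per library in replicate order, folds are ratios of mean FPKM, and adjusted p-values are from limma on log2(FPKM + 1).

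KLF11 encodes a zinc finger transcription factor of the Krüppel-like family that is induced by TGF-beta, and it was the target of the siRNA. Its level was 12.3 and 12.4 FPKM in the control libraries and 5.49 and 6.74 FPKM in the KLF11 siRNA libraries. The means were 12.4 ± 0.078 and 6.12 ± 0.884 FPKM (SD, n = 2 each), so the KLF11 siRNA mean was 0.494 of the control mean. The fitted log2 change was -0.92 (SE 0.139, adjusted p = 0.00951, limma). Without control siRNA replicate 1 or 2 the adjusted p was 0.116 or 0.113, while the sign of the change was kept in every fit with 1 library left out.

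The comparison of the groups asked which transcripts differ when KLF11 is lowered, in a series whose title links low KLF11 to a stem cell-like identity of sarcoma cells and to the activity of YAP. Of 15320 genes tested, 2071 were higher and 3329 lower with KLF11 siRNA, and 716 of the higher and 1265 of the lower genes moved by at least 1 log2 unit. The median log2 change of all tested genes was -0.11. Median-of-ratios scaling, which centres the gene ratios between libraries by construction, gave a median of -0.01, with 2728 genes higher and 2664 lower. TPM scaling gave 1819 higher and 3699 lower. The excess of lower genes thus depends on the scaling, and these fits cannot tell whether it is real. Libraries of the 2 groups did not overlap for 73.4% of tested genes, against 33.3% by chance. With control siRNA replicate 1 or 2 left out, the limma calls of single genes were lost, so these calls depend on each control library. The spread then rests on the KLF11 siRNA pair alone. The log2 change of CTGF was 3.39 or 3.40 in those fits and that of KLF11 -0.92 or -0.91, against 3.40 and -0.92 with every library. An exact permutation test of 2 against 2 libraries cannot go below a two-sided p of 0.333 and was not used for calls.

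Genes known as targets of YAP and its TEAD partners rose on balance. CTGF, which encodes a secreted matricellular protein, went from 22.8 and 23.0 FPKM to 252 and 251 FPKM (10.9-fold higher, adjusted p = 0.000446), and its relative CYR61 from 15.8 and 15.2 to 104 and 94.2 FPKM (6.39-fold higher, adjusted p = 0.00072). RBMS3 rose 4.98-fold and FJX1 2.93-fold, from means near 1.16 and 2.61 FPKM. Across the list of YAP and TEAD targets 11 of 20 tested members rose and 3 fell (12 and 3 adjusted over the list alone), with a median log2 change of 0.56 (camera adjusted p = 0.000181; adjusted p = 0.495 with an estimated correlation). The 3 that fell were MYOF, GADD45A and ARHGEF17. ANKRD1, a widely used YAP target, did not pass, with 28.9 and 31.5 FPKM in control and 17.0 and 43.5 FPKM in KLF11 siRNA libraries (adjusted p = 0.813). Its 2 KLF11 siRNA libraries lay on either side of the controls. Its log2 change was 0.51 without KLF11 siRNA replicate 1 and -0.79 without KLF11 siRNA replicate 2.

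YAP1 itself was lower, at 98.9 and 97.6 FPKM in control and 74.6 and 76.1 FPKM in KLF11 siRNA libraries (log2 change -0.38, adjusted p = 0.0193). That call was lost with median-of-ratios scaling (log2 change -0.26, adjusted p = 0.0527), with a fit without a variance trend (adjusted p = 0.0538), with no filter (adjusted p = 0.0504) and without either control library. WWTR1, which encodes the YAP relative TAZ, did not pass, with means of 12.2 FPKM in control and 15.1 FPKM in KLF11 siRNA libraries (adjusted p = 0.124), nor did TEAD1, with 21.1 and 21.1 FPKM in control and 24.6 and 22.3 FPKM in KLF11 siRNA libraries (adjusted p = 0.306). TEAD4 rose 1.96-fold to 34.9 and 31.3 FPKM. Among Hippo pathway components 5 of 30 tested members rose and 5 fell (5 and 5 adjusted over the list alone), and the list as a whole did not pass (camera adjusted p = 0.378, with the median just below 0, a mean of 0.09 and camera's direction up). FRMD6, TEAD4, VGLL3, FAT1 and FAT4 rose, while STK3, NF2, AMOT, YAP1 and TEAD2 fell. AMOT, an angiomotin that binds YAP, was 3.13-fold lower, and VGLL3 went from 0.43 and 0.40 to 6.80 and 4.37 FPKM. With median-of-ratios scaling 8 components rose and 2 fell.

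**Figure D1:**
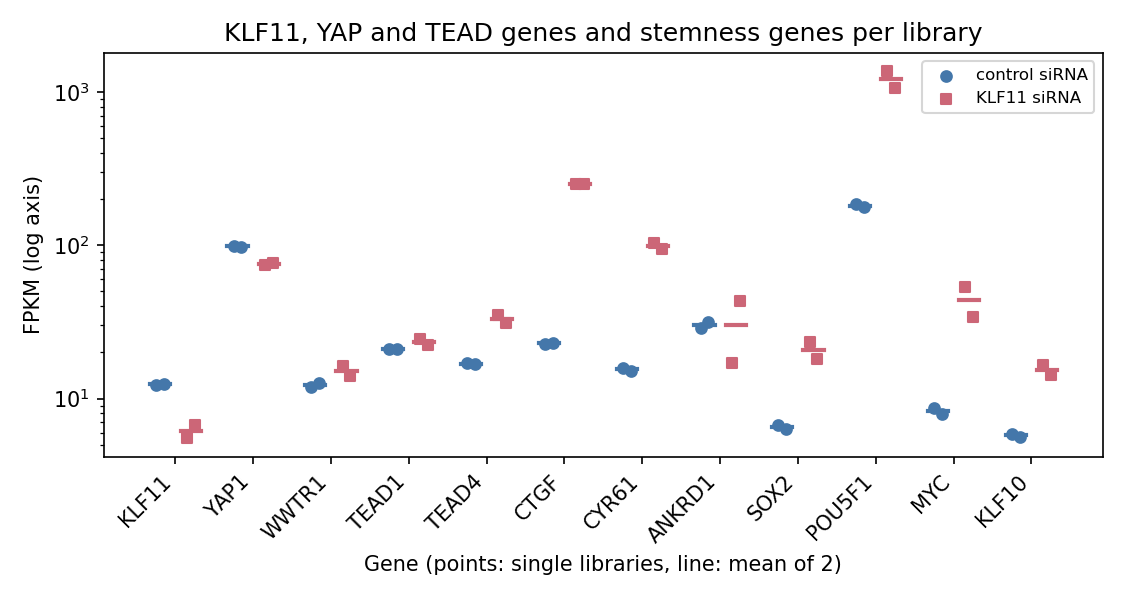
FPKM on a log axis of KLF11, YAP and TEAD genes, YAP targets and stemness genes, with one point per library (circles control siRNA, squares KLF11 siRNA) and a line at the mean of the 2 libraries of a group. CTGF lies at 22.8 and 23.0 FPKM in control and 252 and 251 FPKM in KLF11 siRNA libraries, while the KLF11 siRNA libraries of ANKRD1, at 17.0 and 43.5 FPKM, fall on both sides of the controls.

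Several genes tied to stem cell identity rose strongly. POU5F1, a core transcription factor of pluripotent cells, went from 186 and 177 to 1364 and 1068 FPKM (6.70-fold higher, adjusted p = 0.00145), SOX2 from 6.68 and 6.36 to 23.4 and 18.1 FPKM and MYC from 8.74 and 7.90 to 53.5 and 34.3 FPKM. THY1 rose 7.59-fold and the drug efflux transporter ABCG2 8.84-fold. In the list of stemness-associated genes 12 of 21 tested members rose and 5 fell (12 and 5 adjusted over the list alone), with a median log2 change of 1.27 (camera adjusted p = 0.000752; adjusted p = 0.495 with an estimated correlation). The 5 that fell were SALL4, ALDH1A3, KIT, ITGA6 and LGR5, and KIT, a receptor tyrosine kinase, dropped from 47.5 and 48.9 to 9.76 and 12.6 FPKM. KLF4 was under the filter, with 0.14 and 0.23 FPKM in control and 0.93 and 0.30 FPKM in KLF11 siRNA libraries. Reads of POU5F1 can be shared with its pseudogenes, so its level is uncertain to that extent.

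In these libraries the stemness genes moved beside genes of early endoderm, which were named only after their values had been seen. CER1, a secreted antagonist of Nodal and BMP signals, was at 4430.3 and 4406 FPKM in control and 958 and 2574 FPKM in KLF11 siRNA libraries (adjusted p = 0.0543). It passed with TPM scaling (adjusted p = 0.0448), quantile normalization (0.0276) and a filter of mean FPKM 5 (0.0438). Over the alternatives that kept every library its adjusted p ran from 0.0276 to 0.175 in limma. The log2 change was -0.78 without KLF11 siRNA replicate 1 and -2.20 without replicate 2. A p-value from those fits would rest on the control pair alone, without the gap between the KLF11 siRNA libraries. SOX17, an endoderm transcription factor, fell from 133 and 131 to 19.2 and 47.9 FPKM, and NANOG, a pluripotency factor, rose from 33.9 and 30.4 to 162 and 95.9 FPKM. Both groups of libraries labelled MG63 held these genes.

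Within the KLF and SP family, 3 of 15 tested members rose and 5 fell (3 and 6 adjusted over the list alone), and the list as a whole did not pass (camera adjusted p = 0.839, median log2 change -0.01, mean -0.23 and camera direction up). KLF3, KLF7 and KLF10 rose, and KLF5, KLF6, KLF8, KLF15 and SP8 fell. KLF10, the closest relative of KLF11, went from 5.89 and 5.65 to 16.5 and 14.1 FPKM (2.66-fold higher, adjusted p = 0.00468). KLF8 fell 5.16-fold, from 84.0 and 82.1 to 9.86 and 22.3 FPKM, and KLF6 2.31-fold. KLF14 was not analysed here.

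The largest rise in fitted log2 change was that of SPP1, which encodes the bone matrix protein osteopontin, from 2.31 and 2.76 to 247 and 99.1 FPKM (log2 change 5.48, adjusted p = 0.00299). ACTG2, a smooth muscle actin whose reads can be shared with other actins, went from 1.40 and 1.07 to 59.7 and 61.7 FPKM. ANXA1, an annexin, rose 27.5-fold, IGFBP7, an insulin-like growth factor binding protein, 24.9-fold, DACT1 24.7-fold and OLFML3 23.0-fold. SFTA1P, a transcribed pseudogene, went from 0.76 and 1.07 to 47.9 and 44.2 FPKM and VAT1L from 0.29 and 0.19 to 26.2 and 13.7 FPKM. The identifier ENSG00000238392, which the table pairs with no symbol, was listed at 0 in both control libraries and at 19.9 and 24.1 FPKM with KLF11 siRNA.

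The largest falls included ENSG00000266881, again without a symbol, at 55.4 and 59.5 FPKM in control libraries and listed at 0 in both KLF11 siRNA libraries. ENSG00000221181 went from 51.1 and 48.8 FPKM to 1.40 FPKM in KLF11 siRNA replicate 2 and was listed at 0 in replicate 1. EPSTI1 fell from 74.8 and 74.9 to 0.68 and 7.10 FPKM (log2 change -4.36, adjusted p = 0.0112), and CCKBR, the gastrin and cholecystokinin receptor, from 186 and 172 to 4.73 and 24.8 FPKM. Of the calcium-binding proteins, S100A14 dropped 36.0-fold and S100A16 from 64.1 and 60.3 to 2.14 and 6.62 FPKM. APOA2, an apolipoprotein, fell from 34.6 and 30.4 FPKM to 3.42 FPKM in replicate 2 and was listed at 0 in replicate 1, and AC084816.1 fell from 27.2 and 25.6 to 0.18 and 2.85 FPKM. The other 2 of the 10 largest falls were identifiers without a symbol.

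**Figure D2:**
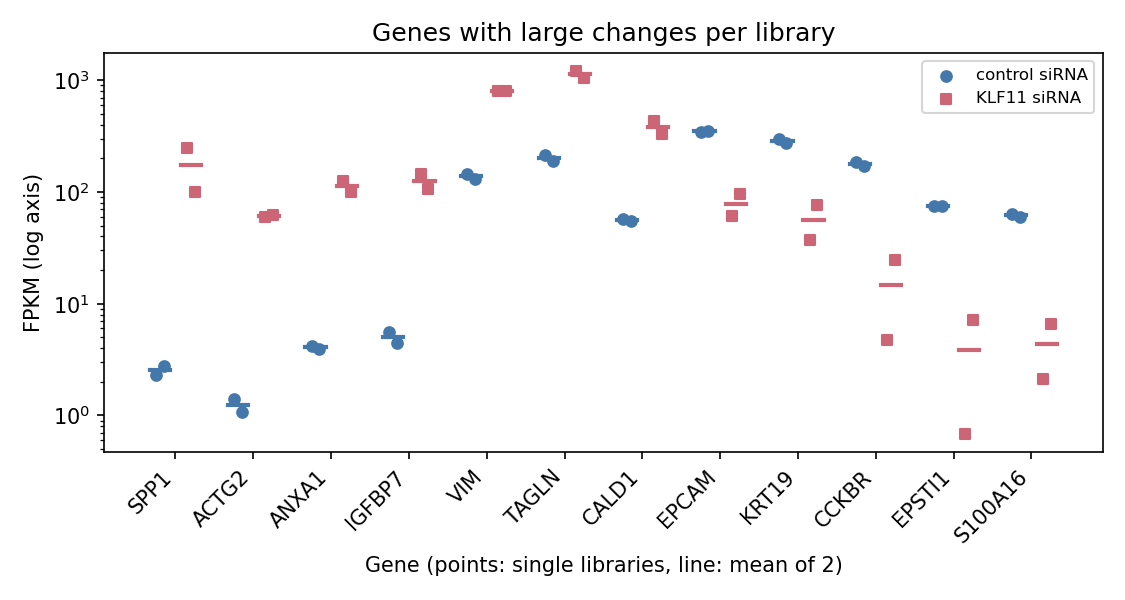
FPKM on a log axis of genes with large changes, with one point per library (circles control siRNA, squares KLF11 siRNA) and a line at the mean of the 2 libraries of a group. VIM lies at 144 and 131 FPKM in control and 808 and 799.9 FPKM in KLF11 siRNA libraries, and EPCAM at 346 and 352 FPKM in control and 60.7 and 95.5 FPKM in KLF11 siRNA libraries.

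Most tested members of the mesenchymal transition and the actin lists rose, and most epithelial markers fell. VIM, an intermediate filament of mesenchymal cells, was 5.84-fold higher (adjusted p = 0.00072), TAGLN 5.59-fold, and CDH11, a mesenchymal cadherin, went from 1.44 and 1.20 to 34.9 and 23.4 FPKM. For mesenchymal transition genes 8 of 13 tested members rose and 2 fell (8 and 3 adjusted over the list alone; camera adjusted p = 0.00486; adjusted p = 0.495 with an estimated correlation), the 2 that fell being CDH2 and S100A4. Of 20 tested genes abundant in mesenchymal cells, a list written after some values had been seen, 5 rose, 3 fell and 12 did not pass. Those that fell were COL1A1, COL6A1 and S100A4. For actin and focal adhesion genes 18 of 28 tested members rose and 1 fell (20 and 1 adjusted over the list alone), with a median log2 change of 0.61 (camera adjusted p = 1.58e-09; adjusted p = 0.495 with an estimated correlation). CALD1 rose 6.75-fold, FLNC 6.26-fold and CAV1, which coats caveolae, 9.70-fold. Among epithelial markers 0 of 11 tested members rose and 10 fell (0 and 11 adjusted over the list alone), with a median log2 change of -1.19 (camera adjusted p = 9.73e-05; adjusted p = 0.546 with an estimated correlation). EPCAM dropped from 346 and 352 to 60.7 and 95.5 FPKM, KRT19 from 300.0 and 275 to 36.8 and 76.1 FPKM, CLDN3 10.1-fold and ELF3 6.30-fold. SOX17 fell in the same libraries, and CER1 measured 958 and 2574 FPKM there.

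Matrix genes went both ways. For collagens and matrix 7 of 22 tested members rose and 6 fell (7 and 8 adjusted over the list alone), with a median log2 change of -0.14, a mean of 0.28 and camera's direction up (adjusted p = 0.492). VCAN rose 3.83-fold, FBN1 6.10-fold and the collagen cross-linking enzyme LOXL2 3.27-fold, while COL4A1, a basement membrane collagen, fell 2.52-fold. Of matrix proteases and inhibitors, 9 of 14 tested members rose and 0 fell (9 and 1 adjusted over the list alone; camera adjusted p = 0.000144; adjusted p = 0.495 with an estimated correlation), including the gelatinase MMP2 from 16.3 and 12.5 to 161 and 91.5 FPKM, SERPINE2 3.14-fold and PLAU, the urokinase, 2.45-fold. TGF-beta response genes gave a smaller shift, in that 9 of 25 tested members rose and 3 fell (9 and 3 adjusted over the list alone) with a median log2 change of 0.16 (camera adjusted p = 0.0123; adjusted p = 0.495 with an estimated correlation). TGFBI rose 3.32-fold and THBS1 2.51-fold, and SMAD6, SMAD3 and FSTL3 fell.

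Of osteoblast lineage genes 5 of 11 tested members rose and 2 fell (5 and 2 adjusted over the list alone; camera adjusted p = 0.021; adjusted p = 0.546 with an estimated correlation). SPP1, TNFRSF11B, ATF4 and FOSL2 were among those that rose, TNFRSF11B, which encodes the decoy receptor osteoprotegerin, from 6.12 and 5.53 to 23.5 and 21.8 FPKM, and COL1A1 and BMP2 fell. That list did not pass camera with quantile normalization (adjusted p = 0.0961), with a filter of mean FPKM 5 (adjusted p = 0.073) or without KLF11 siRNA replicate 1 (adjusted p = 0.0548). For endothelial and mural markers 3 of 7 tested members rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.0354; adjusted p = 0.495 with an estimated correlation), a call lost with median-of-ratios scaling (adjusted p = 0.0719), with quantile normalization (adjusted p = 0.0848), with the filter at 5 FPKM (adjusted p = 0.194) and without KLF11 siRNA replicate 1 (adjusted p = 0.152). FLT1, TEK and MCAM rose, FLT1 8.31-fold, and VWF fell. For neural and muscle markers 2 of 8 tested members rose and 2 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.86), with MAP2 and ACTC1 higher and TUBB3 and SOX10 lower; the median log2 change was -0.30, the mean 0.07 and camera's direction down. No leukocyte marker reached the filter, the highest of the 15 being at 0.85 FPKM. Only 4 cartilage and fat markers did, of which MATN3 fell.

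Cell cycle genes rose by modest amounts. In the S phase list 17 of 29 tested members rose and 1 fell (19 and 2 adjusted over the list alone), with CCNE1 as the fall and a median log2 change of 0.49 (camera adjusted p = 1.22e-07; adjusted p = 0.495 with an estimated correlation). PCNA, the sliding clamp of DNA polymerase, was 2.35-fold higher, TYMS 2.10-fold, RRM2 1.64-fold and MCM4 1.75-fold. In the G2/M list 30 of 41 tested members rose and 0 fell (36 and 0 adjusted over the list alone), with a median of 0.48 (camera adjusted p = 3.62e-12; adjusted p = 0.495 with an estimated correlation), and CENPF rose 1.88-fold, ECT2 1.61-fold, LBR 1.90-fold and TOP2A 1.53-fold. In a list of CDK inhibitors and others 12 of 23 tested members rose and 5 fell (14 and 6 adjusted over the list alone), with a median log2 change of 0.69 (camera adjusted p = 0.00223; adjusted p = 0.546 with an estimated correlation; adjusted p = 0.0723 in fry). Of it GDF15, a stress-induced cytokine, went from 1.36 and 1.52 to 11.3 and 15.2 FPKM, RRM2B rose 3.33-fold and TNFRSF10B 1.90-fold, whereas CDKN1B, CDKN1C, BBC3, BTG2 and GADD45A fell. Apoptosis regulators moved both ways, so that 7 of 21 tested members rose and 8 fell (7 and 9 adjusted over the list alone; camera adjusted p = 0.634, median log2 change -0.03 with camera's direction up). PMAIP1 rose 2.44-fold, and the caspase inhibitor CFLAR fell 4.29-fold and BAD 2.16-fold.

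**Figure D3:**
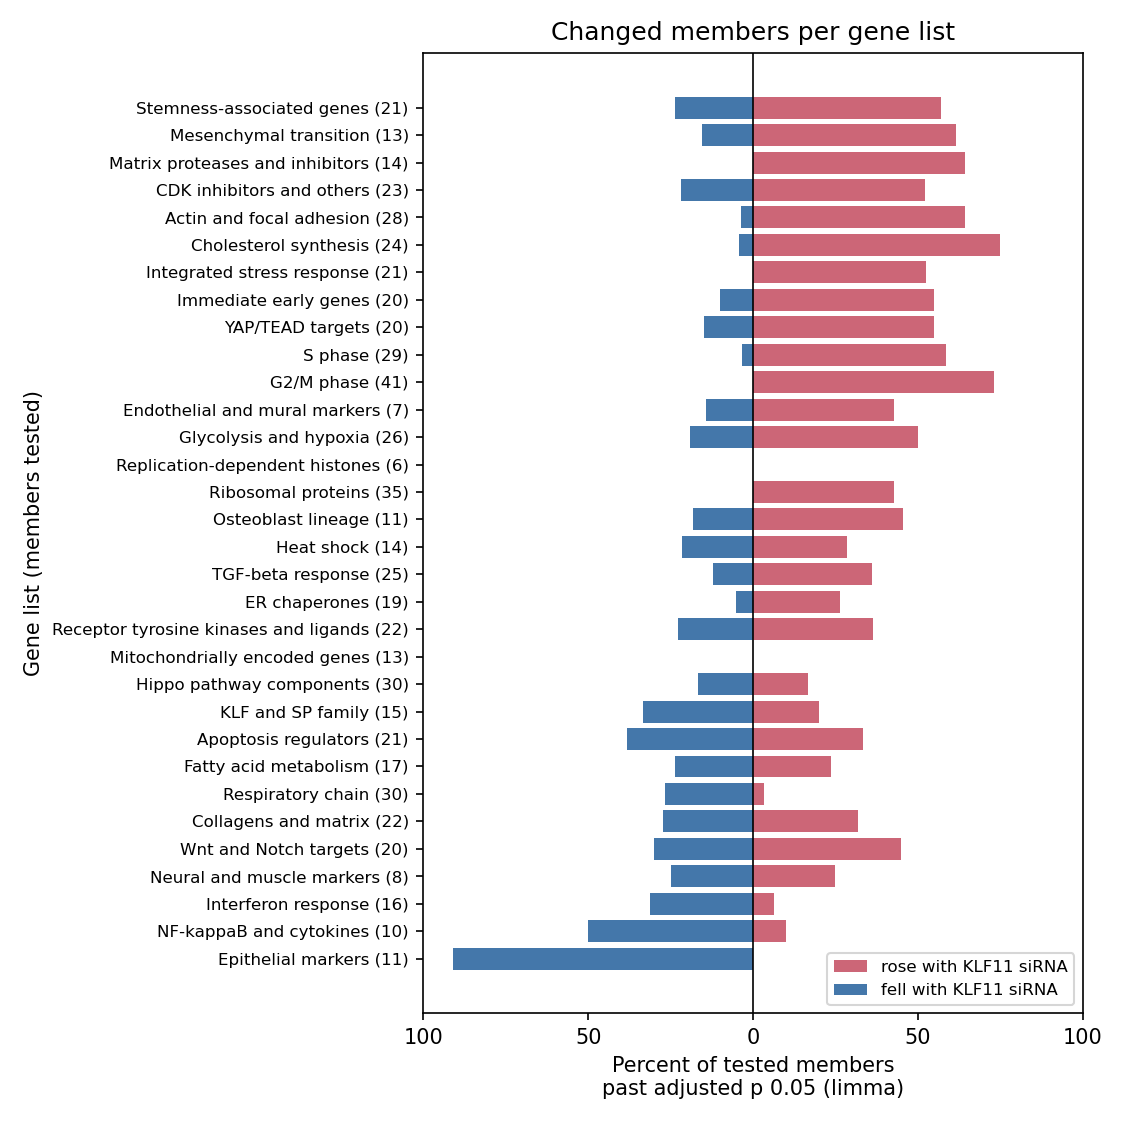
Percent of the tested members of each of 32 gene lists that fell (left) or rose (right) with KLF11 siRNA at an adjusted p under 0.05 in limma, lists ordered by their median log2 change and followed by the number of members tested. Of 41 G2/M genes 30 rose and 0 fell, and of 11 epithelial markers 0 rose and 10 fell.

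Immediate early and growth factor feedback genes, fixed as a single list, rose on balance. DUSP6, an ERK phosphatase, went from 25.4 and 20.3 to 213 and 196 FPKM (adjusted p = 0.00119), SPRY4 rose 6.34-fold, ETV4 2.80-fold and ETV5 2.33-fold. In the immediate early list 11 of 20 tested members rose and 2 fell (11 and 3 adjusted over the list alone; camera adjusted p = 0.000198; adjusted p = 0.546 with an estimated correlation), the falls being DUSP4 and NR4A1. Of receptor tyrosine kinases and ligands 8 of 22 tested members rose and 5 fell (8 and 6 adjusted over the list alone; camera adjusted p = 0.335), with FGF2 from 1.82 and 2.18 to 24.0 and 13.8 FPKM and PDGFA 4.73-fold higher, and FGFR2, FGFR3, KIT, NRG1 and GAS6 lower. Wnt and Notch targets also split, in that 9 of 20 tested members rose and 6 fell (9 and 6 adjusted over the list alone; camera adjusted p = 0.378, median log2 change -0.15, mean 0.18 and camera's direction up). The Wnt antagonist DKK1 rose 4.41-fold, HES1 4.39-fold and SP5 3.46-fold, and NKD2 fell 3.67-fold.

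Cholesterol synthesis genes rose on balance: of this list 18 of 24 tested members rose and 1 fell (18 and 1 adjusted over the list alone), with TM7SF2 as the fall and a median log2 change of 0.59 (camera adjusted p = 1.02e-07; adjusted p = 0.495 with an estimated correlation). SC5D rose 3.21-fold, INSIG1 2.24-fold, IDI1 2.23-fold and HMGCS1 2.03-fold. For the integrated stress response 11 of 21 tested members rose and 0 fell (13 and 1 adjusted over the list alone; camera adjusted p = 7.47e-06; adjusted p = 0.546 with an estimated correlation), including genes of serine, folate and asparagine synthesis: PHGDH rose 2.75-fold, PSAT1 4.14-fold, MTHFD2 2.37-fold and ASNS 5.17-fold. For glycolysis and hypoxia 13 of 26 tested members rose and 5 fell (13 and 6 adjusted over the list alone; camera adjusted p = 0.00931; adjusted p = 0.546 with an estimated correlation; adjusted p = 0.0981 in camera after quantile normalization). The glucose transporter SLC2A1 went from 13.2 and 11.3 to 100.3 and 97.5 FPKM, PDK1 from 11.9 and 12.1 to 49.3 and 46.9 FPKM, and HK1 rose 2.86-fold, while PFKL, PFKM, SLC2A3, VEGFA and PFKFB4 fell. VEGFA, the angiogenic growth factor, dropped from 73.7 and 69.8 to 6.09 and 10.1 FPKM. For fatty acid metabolism 4 of 17 tested members rose and 4 fell (4 and 5 adjusted over the list alone; camera adjusted p = 0.634, direction up against a median log2 change of -0.05). SCD, FADS2, ACSL3 and CPT1A rose and ACSL1, ACADM, PLIN2 and LPIN1 fell. For the respiratory chain 1 of 30 tested members rose and 8 fell (1 and 7 adjusted over the list alone; camera adjusted p = 0.602), NDUFA9 being the rise and UQCRC1 falling 1.47-fold; with median-of-ratios scaling 4 rose and 4 fell, so that direction was not kept.

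Among interferon response genes 1 of 16 tested members rose and 5 fell (1 and 8 adjusted over the list alone; camera adjusted p = 0.228), IFIT3 being the rise. BST2, which tethers virus particles to the cell surface, dropped from 35.5 and 32.9 to 1.03 and 4.32 FPKM, STAT2 1.86-fold and DDX58 3.15-fold, and IRF9 also fell. The interferon list passed in the directional fry test (adjusted p = 0.025) and in camera with the filter at 5 FPKM (adjusted p = 0.00719). Of NF-kappaB and cytokine genes 1 of 10 tested members rose and 5 fell (1 and 6 adjusted over the list alone; camera adjusted p = 0.331). The chemokine CCL2 dropped from 62.6 and 62.8 to 2.13 and 7.44 FPKM, NFKBIA 3.33-fold and NFKB2 2.08-fold, RELB and ICAM1 fell as well, and IL11 rose from 0.69 and 0.82 to 2.27 and 2.67 FPKM.

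Ribosomal protein genes were slightly higher, in that 15 of 35 tested members rose and 0 fell (30 and 0 adjusted over the list alone) with a median log2 change of 0.37 (camera adjusted p = 1.43e-09; adjusted p = 0.546 with an estimated correlation; adjusted p = 0.0532 in camera after quantile normalization, with a median of 0.13; adjusted p = 0.0794 in fry). The number of rises depended on scaling, with 30 under median-of-ratios scaling, 9 under TPM scaling and 4 under quantile normalization. RPS3 was 1.56-fold, RPL27 1.49-fold and RPL32 1.43-fold higher, and many ribosomal pseudogenes can share their reads. The calls of RPS3 and RPL32 were lost with quantile normalization (adjusted p = 0.163 and 0.0618, limma). With no filter RPS3, RPL27 and RPL32 each lost the call (adjusted p = 0.0746, 0.0635 and 0.0648, limma). For ER chaperones 5 of 19 tested members rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 0.037; adjusted p = 0.681 with an estimated correlation), with PDIA3, PDIA4, DNAJB11, HERPUD1 and XBP1 higher and SEL1L 1.69-fold lower. The calls of PDIA3, PDIA4 and XBP1 were lost without KLF11 siRNA replicate 1 (adjusted p = 0.0609, 0.0807 and 0.0513), with no filter (adjusted p = 0.0789, 0.0896 and 0.0523) and without either control library, those of PDIA3 and PDIA4 also without a variance trend (adjusted p = 0.0599 and 0.0803) and that of PDIA4 with TPM scaling (adjusted p = 0.0627). The ER chaperone call was lost with TPM scaling (adjusted p = 0.063, and 0.0573 without mitochondrially encoded genes), without a variance trend (adjusted p = 0.0559), with a filter of mean FPKM 5 (adjusted p = 0.0563), with quantile normalization (adjusted p = 0.307), without control siRNA replicate 1 (adjusted p = 0.066) and without KLF11 siRNA replicate 1 (adjusted p = 0.101), all in camera, and in fry (adjusted p = 0.213). For heat shock genes 4 of 14 tested members rose and 3 fell (4 and 3 adjusted over the list alone, camera adjusted p = 0.228). The median log2 change of that list was 0.23, and 0.37 without KLF11 siRNA replicate 2. The mitochondrial chaperonins HSPE1 and HSPD1 rose 2.10-fold and 1.91-fold, HSPA8 and HSP90AB1 also rose, and HSPA1A, HSPA1B and HSPB1 fell, of which HSPA1A and HSPA1B are near-identical copies that share reads. No member of the 6 tested replication-dependent histone genes passed (median log2 change 0.38, camera adjusted p = 0.25). Without KLF11 siRNA replicate 2 that median was 0.53. The log2 changes of HIST1H2BK and HIST1H2BJ were then 0.63 and 0.68, against 0.37 and 0.39 with every library. Of 13 mitochondrially encoded genes 0 passed (median log2 change 0.05, camera adjusted p = 0.378). Without KLF11 siRNA replicate 1 the median log2 change of the mitochondrially encoded genes was 0.33. MT-CO1 passed as a fall with quantile normalization (adjusted p = 0.0303, limma), and its log2 change was -0.985 without KLF11 siRNA replicate 2. The share of mitochondrially encoded genes in summed FPKM was 6.44% and 9.01% in control and 5.89% and 9.57% in KLF11 siRNA libraries, higher in replicate 2 of both groups. With the replicate number as a block MT-ND2 passed as a rise (log2 change 0.40, adjusted p = 0.0282, limma).

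Of the 32 lists tested, 17 passed camera upward and 1, the epithelial markers, downward. With an estimated correlation, where camera has 2 residual degrees of freedom, 0 lists passed. That correlation ran from -0.11 for endothelial and mural markers to 0.972 for mitochondrially encoded genes. It was 0.881 for epithelial markers, 0.838 for ribosomal proteins and -0.049 for YAP and TEAD targets. Where it lies far above the preset 0.01, the p-values at the preset treat genes that move together as nearly independent. The directional fry test, which asks whether a list's genes move on balance one way, passed for 16 lists, and its mixed form, which asks whether they change in either direction, for 30. Names given for members behind counts of 5 or fewer were chosen after their values were seen.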

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

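TPM scaling without mitochondrially encoded genes was chosen after the data were seen. Over 3578 comparisons of named genes and lists with an alternative, 3058 stayed on the same side of the threshold, among them genes and lists without a call whose sign changed. In the same direction, 470 lost the call and 49 gained one, and 1 reversed; 347 of the losses came from leaving out a control library. The reversed one is ANKRD1, with a log2 change of 0.51 without KLF11 siRNA replicate 1, the library left out lying below the controls. The spread in that fit rests on the control pair alone.

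The 5400 changed genes (2071 higher, 3329 lower) became 1981 (716 and 1265) with a minimum log2 change of 1, and 2138 (887 and 1251) with no filter, where 34232 genes were tested. With 1 library left out, the lone library being assumed to vary like the other group, the count ran from 0 to 6104 (higher 0 to 2291, lower 0 to 3813). The 0 came without control siRNA replicate 1 or 2, with 4461 and 4793 genes at an unadjusted p under 0.05 in limma; the spread then rests on the KLF11 siRNA pair alone. Without KLF11 siRNA replicate 1 or 2 the count was 3958 or 6104. With 1 library left out the KLF11 log2 change ran from -1.04 to -0.79 and missed the threshold without either control, and over the other alternatives its smallest size was -0.65, with a pseudocount of 5.

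With an estimated correlation camera passed 0 lists, losing the YAP/TEAD targets (median log2 change 0.56) and the stemness list (1.27), each at adjusted p = 0.495; it then has 2 residual degrees of freedom. The mixed fry test passed 30. With a pseudocount of 5 the median SD of the KLF11 siRNA pair was 0.0840. Deviations of same-numbered libraries correlated at -0.07, which over 2 pairs cannot decide whether the numbers mark a shared batch. The share of mitochondrially encoded genes was higher in replicate 2 of both groups (6.44% and 9.01% in control, 5.89% and 9.57% in KLF11 siRNA libraries). With the replicate block 4351 genes passed (1707 higher, 2644 lower), 4210 of them shared with the fit without it. Under that block CER1 passed (adjusted p = 0.0325) and EOMES did not (adjusted p = 0.06, both limma). Read depth is unknown, so its limits cannot be given.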

Other observations

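In this part, the tests on the distance of KLF11 siRNA replicate 2 from the controls and on the direction of endoderm genes were chosen after the results were seen. Marker lists for pluripotent, early endoderm and mesenchymal cells were written after a few of their members had been seen and before the rest were.

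Libraries labelled MG63 held genes of pluripotent and early endoderm cells at high levels in both groups. In control libraries TDGF1, a Nodal co-receptor, was at 603 and 631 FPKM, LIN28A at 385 and 396 FPKM, EOMES at 219.8 and 222 FPKM, MIXL1 at 207 and 226 FPKM and FGF17 at 604 and 577 FPKM. CER1 stood at 4430.3 and 4406 FPKM, FOXA2 at 47.6 and 44.1 and GATA4 at 108 and 104 FPKM. In the same libraries COL3A1 was at 0.01 FPKM and listed at 0, LGALS1 at 7.13 and 9.29 FPKM, S100A6 at 3.89 and 3.47 FPKM and CD44 at 2.50 and 1.35 FPKM, while SPARC at 657 and 637, COL5A2 at 306 and 312 and COL1A2 at 133 and 126 FPKM were abundant. CDKN2A went from 0.18 and 0.31 to 6.28 and 2.81 FPKM.

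With KLF11 siRNA, 11 of 16 tested endoderm genes fell and 3 rose, while 9 of 22 pluripotency genes rose and 6 fell. Of mesenchymal genes, 5 of 20 rose and 3 fell. FOXA2 fell 5.26-fold and OTX2 2.91-fold, and GDF3 rose 4.15-fold and DNMT3B 1.92-fold. The 3 endoderm rises were EOMES, MIXL1 and AFP. AFP was listed at 0 in the control libraries. All 3 rises and 9 of the 11 falls lost their call with no filter, and all 14 without either control library, so these alternatives do not set the rises apart. EOMES also lost it with TPM scaling (adjusted p = 0.0631, limma), with that scaling without mitochondrially encoded genes (0.0623), quantile normalization (0.0996), no variance trend (0.0917) and without KLF11 siRNA replicate 1 (0.0568) or 2 (0.0639). MIXL1 lost it with quantile normalization (adjusted p = 0.0833, limma), no variance trend (0.0788), TPM scaling without mitochondrially encoded genes (0.0723) and without KLF11 siRNA replicate 2 (0.0547), and AFP with a pseudocount of 5 (0.0676). Of the falls, FLRT3 lost it with no variance trend (adjusted p = 0.0651, limma), median-of-ratios scaling (0.0565) and quantile normalization (0.0523), and RHOBTB3 with robust estimation (0.0534). Some pluripotency calls were lost as well. The rise of L1TD1 was lost with TPM scaling (adjusted p = 0.0727, limma) and no variance trend (0.0892). The falls of LIN28A and VRTN were lost with median-of-ratios scaling (0.134 and 0.0837) and no variance trend (0.0833 and 0.0761). With no filter DPPA4, ZFP42 and CDH1 also lost their calls (0.0595, 0.0916 and 0.104). Epithelial markers hold EPCAM and CDH1 in common with the pluripotency list.

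The high level of these genes was weighed against 3 explanations. Shared reads of pseudogenes are argued against, since 28 genes of the pluripotency and endoderm lists other than POU5F1, NANOG and DPPA4 exceeded 10 FPKM in both control libraries. That the libraries come mostly from another cell type than the label says stays open: the mesenchymal list had 0.336 times the median control FPKM of the pluripotency list, as that explanation predicts, but COL1A1 at 22.8 and COL1A2 at 129.7 FPKM exceeded the 10 FPKM set beforehand as its limit. A small share of such cells in an osteosarcoma culture is argued against for the genes of these lists, since the mark set beforehand against it was met. The mesenchymal list's median was 19.8 and 17.4 FPKM in control siRNA replicates 1 and 2. The median over the control means, 18.6 FPKM, lay under that mark of 30 FPKM. It also lay under the control medians of the pluripotency and endoderm lists, 55.4 and 58.7 FPKM. Its 95% interval over the list's genes, which were chosen and not sampled, ran from 1.93 to 226 FPKM. Of the 24 listed mesenchymal genes, 13 exceeded 10 FPKM in both control libraries, so the median alone does not settle what the cells were. What the cells were may therefore bear on every comparison above, and no biological explanation was tested.

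KLF11 siRNA replicate 2 lay nearer to the controls than replicate 1, for 79.0% of the genes that fell and 79.1% of those that rose. Control-like cells or reads mixed in at a single share are argued against as the whole cause by 63 genes that fell at least 8-fold in replicate 1. The share of control each of them implies had an interquartile range of 0.107 (bootstrap 95% interval 0.0707 to 0.133), above the limit of 0.05 set for a common share. That limit was set after the results were seen and not from a measured noise level. The bootstrap also treats genes that move together as independent. Over the 1439 genes that fell from above 20 FPKM the interquartile range was 0.209. That wider set holds smaller falls, for which noise alone spreads the implied share, so its range does not decide. A weaker knockdown stays open, with KLF11 1.25 FPKM higher in replicate 2. KLF11 is itself among the genes that fell, 79.0% of which were higher there, so its level cannot single out that cause. Besides, 2 libraries are too few to decide.

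The fall of endoderm genes beside higher POU5F1, NANOG and SOX2 is not removed by scaling. The endoderm list's median log2 change was -1.79 as deposited and -1.71 with median-of-ratios scaling, and -2.01 and -1.66 with TPM and quantile scaling. The pluripotency list's medians were 0.12, 0.24, 0.08 and 0.23 in that order, against -0.11, -0.01, -0.16 and 0.01 for all tested genes. POU5F1, NANOG and SOX2 thus do not stand for the pluripotency genes as a set. A group difference in stage of culture or differentiation at harvest, apart from the siRNA, cannot be told apart from an effect of the siRNA. The labels give no stage for any library, and 11 endoderm genes fell in the tests above. The endoderm list's median was 9.62 and 29.3 FPKM in KLF11 siRNA replicates 1 and 2, against 59.4 and 58.0 FPKM in control. Endoderm levels thus differed between libraries given the same siRNA. Whether stage or knockdown set that gap cannot be told. An effect of lower KLF11 is a hypothesis that remains open beside a difference in stage, and a second siRNA was not analysed here.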
